A study of Homo sapiens with 12 samples.

How the data were processed

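Poly(A) RNA was sequenced from 12 libraries of TMD8, an established human cell line from a diffuse large B cell lymphoma of the activated B cell type. Per the labels, 6 libraries came from cells carrying a short hairpin RNA (shRNA, which lowers the messenger RNA of its target) against IRF4 and 6 from cells carrying a scramble shRNA with no intended target. Cell pellets were taken at 24 h, libraries were made with a TruSeq stranded kit, in which the read orientation marks the transcribed strand, and sequencing was paired-end with reads of 100 bp, per the labels' protocols. A characteristic of the samples carried a cell line name whose number ran upward from TMD8 with the sample, while every title said TMD8, so all libraries were taken as TMD8.

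Per the submitters' processing notes, STAR, HTSeq and the genome build hg38 were used, with no versions and no order of steps given. The deposited table held estimated (expected) counts for 26318 genes in 12 columns, with no normalization by the authors. Of its values 66.6% were whole numbers at a tolerance of 1e-06. HTSeq as usually run gives whole counts, so the step that produced fractional values is not given in the sources used here, nor is the annotation release or whether the counting used strand. Fractional counting can split reads between a gene and its near-identical copies, and without strand a gene cannot be told from an antisense partner. The chromosome, start and end of each gene were taken from the deposited table, in which the end lies 1 past the last base and was reduced by 1. Of the gene names, 24813 were found in GENCODE release 29 for the same build, and 18401 of these had the same start.

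The estimated counts as deposited were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood fit without robust estimation, TMM normalization, genes kept by filterByExpr with its minimum count of 10) in R 4.3.3. This left 16437 genes. Benjamini-Hochberg adjusted p-values under 0.05 were counted as changed, and positive log2 fold changes are higher with IRF4 shRNA. Standard errors (SE) of fold changes are the log2 fold change divided by the square root of the F statistic. Levels are counts per 1e6 counts (CPM) on TMM-scaled library sizes, as mean ± SD. The target gene was also compared by exact two-sided permutation of log2 CPM.

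Library names held a number 1 or 2, whose meaning (hairpin, culture or batch) is not given in the sources used here. These sets of 3 control and 3 IRF4 shRNA libraries are called library series 1 and 2. The contrast was fitted over all libraries without a covariate, within each series, and as an interaction of series and group, where a positive value is a higher effect in series 2. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries of a group and series differed by more than sampling noise (chi-square per degree of freedom of 2.75 to 32.5 over genes with at least 20 counts). This spread does not show separate cultures, and each library was counted as 1 sample.

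Counts per library ran from 31.3 to 38.2 M (M, 1e6 counts). A floor of 3 counts corresponded to 0.0786 to 0.0959 CPM. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. On simulated counts with known changes in 100 genes per size, run over 16437 genes, the comparison over 12 libraries recovered 64% of changes of 0.5 and 89% of changes of 1 on the log2 scale, with 3.16% of calls false. Each series alone recovered 36% and 37% of the smaller and 73% and 74% of the larger changes, for series 1 and 2, with 4.39% and 3.48% of calls false. The interaction recovered 15% and 67%, with 7.78% of calls false. These simulations changed few genes and held no shared trend with series, culture or GC, so their shares need not hold for the real calls. In a simulation that moved the interferon list, camera called it and 1 of the 27 other lists, the other IRF family members, which share genes with it.

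Before the data were examined, 28 gene lists, the tests, most alternatives and a rule for the genes named were fixed. The rule took 14 anchor genes, the 10 largest rises and 10 largest falls that passed the test at a mean of at least 1 CPM with the same sign in both series, up to 4 members with the smallest p of each list described, up to 10 genes with the smallest interaction p, and the 10 most abundant genes. Genes without a symbol and pseudogenes were skipped among rises and falls. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes on log2 CPM with a prior count of 2, adjusted over the 28 lists. Camera asks whether a list moved relative to other genes. It was repeated with a correlation estimated per list, and fry tested whether a list's genes moved on balance 1 way.

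Alternatives were DESeq2 1.42.0 (its size factors in edgeR and its Wald test), limma-voom, library size without a composition factor, no filter on low counts or at least 1 CPM in 6 libraries, removal of the 10 most abundant genes, a series term, replicate blocks, counts summed per group and series, a within-series correlation by duplicateCorrelation, and each library left out. Chosen after the data were seen were the removal of control replicates 5 and 6 together, the removal of each library's trend with transcript GC content (known for 96.3% of tested genes), and a replicate block for the gene lists. Figures were drawn with matplotlib 3.10.9. Single transcripts and splicing were not analysed here, and 1 of the gene lists and some of the genes that the rule names are not reported here.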

Results

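Transcript levels were measured in TMD8 cells, a lymphoma line of activated B cell type in which IRF4, a transcription factor of plasma cell and activated B cell programmes, is highly expressed. There were 6 libraries with a scramble shRNA (control) and 6 with an shRNA against IRF4. Total counts were 34.0 ± 2.04 M per control library and 34.8 ± 2.10 M per IRF4 shRNA library (M, 1e6 counts; SD, n = 6 each). The most abundant transcript was mitochondrial MT-CO1 (23534 CPM in controls and 23744 CPM with IRF4 shRNA), and mitochondrial genes took 8.45% ± 0.257 and 8.43% ± 0.175 of counts. Pseudogenes took 6.33% ± 0.136 of counts in controls and 4.77% ± 0.0565 with IRF4 shRNA. The libraries differed in how counts deviated with transcript GC content. Across genes, which are not independent replicates, Spearman's rho of a gene's deviation from its group mean with GC ran from -0.50 (control replicate 3) to 0.60 (control replicate 6) among controls and from -0.33 to 0.31 among IRF4 shRNA libraries. Among IRF4 shRNA libraries it was 0.24 to 0.31 in library series 1 and -0.33 to -0.19 in series 2. Among controls it was -0.50 to -0.045 in series 1, and -0.35, 0.42 and 0.60 in replicates 4, 5 and 6 of series 2.

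IRF4 messenger RNA, the target, was lower in every IRF4 shRNA library than in any control. The gene lies on chromosome 6 from 391752 to 411443 on the plus strand (hg38). It averaged 1481 ± 55.9 CPM in controls and 611 ± 101 CPM with IRF4 shRNA (SD, n = 6 each), or 41.3% of the control level, a log2 fold change of -1.28 (SE 0.09, edgeR adjusted p = 1.41e-08). The exact two-sided permutation test gave p = 0.00216, the smallest it can give. IRF4 fell to 34.7% of control in series 1 (519 ± 10.3 against 1495 ± 72.4 CPM, n = 3 each) and to 47.9% in series 2 (703 ± 13.3 against 1467 ± 44.9 CPM, n = 3 each). Within a series the exact permutation p was 0.1, the smallest that 3 against 3 can give. The difference between the series was 0.46 on the log2 scale (edgeR interaction adjusted p = 0.0011).

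**Figure D1:**
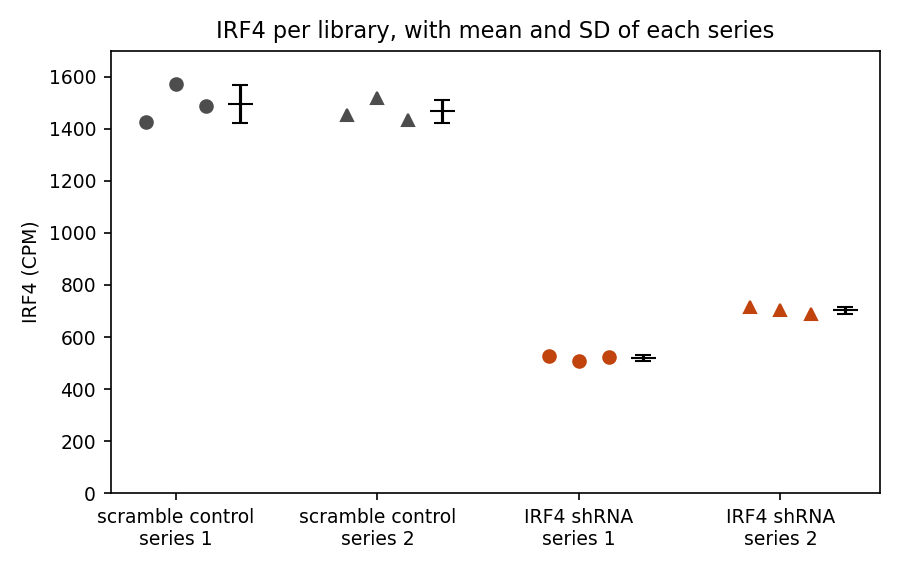
IRF4 level in CPM (vertical axis) in each library, by group and library series; circles are series 1, triangles series 2, and bars are the mean ± SD of 3 libraries. The 6 IRF4 shRNA libraries lie between 507 and 716 CPM and the 6 controls between 1427 and 1571 CPM.

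The main question was which genes differed between IRF4 shRNA and control. Interferon-stimulated genes, chemokine genes and germinal centre B cell genes were on balance higher with IRF4 shRNA, while genes of plasma cell differentiation, the unfolded protein response, the amino acid response and cytosolic ribosomal proteins were lower. By camera with an estimated correlation only the interferon and chemokine lists passed, and the others had adjusted p from 0.0521 to 0.079. IFI27, a mitochondrial protein gene induced by interferon, rose from 2.12 ± 0.505 to 276 ± 6.14 CPM (129-fold). GZMB, which encodes the protease granzyme B, fell from 201 ± 16 to 18.6 ± 11.1 CPM (10.7-fold; n = 6 each for both genes). By edgeR, 7918 of 16437 genes (48.2%) changed, 3983 upward and 3935 downward. Changes of at least 2-fold were more often rises (928) than falls (451). In 5068 genes (30.8%) the 2 groups did not overlap at all, against 0.216% by chance if the libraries are independent samples. With library size alone in place of TMM, 63.9% of calls were rises, against 50.3%, and after the GC trend was removed 42.1% were. With counts summed per group and series (2 against 2), 4242 genes passed.

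Several of the largest rises were interferon-induced genes. Besides IFI27 (chromosome 14, 94104836 to 94116698), IFI44L rose 98.0-fold, from 0.640 ± 0.167 to 62.6 ± 5.97 CPM, and IFI44 90.3-fold, from 0.241 ± 0.104 to 22.1 ± 2.43 CPM. STUM (chromosome 1, 226548764 to 226609230) rose from 0.0838 ± 0.0825 CPM, about the counting floor, to 16.3 ± 3.04 CPM, with a log2 fold change of 7.59 (SE 0.28). OTOF, known for its part in synaptic release in hair cells, rose 97.2-fold to 127 ± 15.5 CPM. CD52, a lymphocyte surface glycoprotein, rose 88.0-fold to 39.7 ± 3.90 CPM. TXNIP (chromosome 1, 145992435 to 145996579), an inhibitor of glucose uptake, rose 77.9-fold, from 2.05 ± 0.247 to 160 ± 5.78 CPM, with an edgeR adjusted p of 2.02e-17. SCIMP, an immune cell adaptor, rose 77.8-fold to 14 ± 0.949 CPM. TMEM229B and PIK3R6 also rose, from only 4 and 7 counts in the 6 controls together to 555 and 702 counts, so the size of their fold changes (log2 6.78 ± 0.50 and 6.41 ± 0.46 SE) is poorly set.

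The largest falls included genes of receptors and signalling. PTGDR, a prostaglandin D2 receptor (chromosome 14, 52267698 to 52276724), fell 19.2-fold, from 17.1 ± 1.53 to 0.878 ± 0.391 CPM. The potassium channel gene KCNA3 fell 11.9-fold, from 23.9 ± 1.85 to 2.0 ± 0.781 CPM, and FRMPD1 10.9-fold, from 22.9 ± 0.751 to 2.09 ± 0.451 CPM. CLEC4C, a lectin receptor best known from plasmacytoid dendritic cells, fell 12.1-fold from 3.43 ± 0.349 CPM, and TGFA, an EGF receptor ligand, fell 10.5-fold from 5.91 ± 0.478 CPM. PSD2 fell 15.2-fold from 4.82 ± 0.691 CPM and GUCA1A 18.1-fold from 2.42 ± 0.390 CPM, to 67 and 28 counts over the 6 IRF4 shRNA libraries. The non-coding DLX6-AS1 fell 8.87-fold, from 9.72 ± 1.28 to 1.09 ± 0.223 CPM, with its antisense partner not told apart where strand was not counted. HSPA1A, which shares reads with its near-identical copy HSPA1B, had a log2 fold change of -3.16 (SE 0.90, edgeR adjusted p = 0.00898) that rested on control replicate 1. Without that library it was -1.60 (adjusted p = 0.0354), and over all alternatives the adjusted p ran from 0.00368 to 0.184.

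All 45 tested members of the type I interferon response list rose, also when adjusted over the list alone, 37 of them at least 2-fold, with a median log2 fold change of 2.18. Camera gave adjusted p = 1.9e-36, and adjusted p = 0.0101 with an estimated correlation. The antiviral genes OAS3 and IFIT1 rose 12.6-fold (25.7 ± 1.75 to 324 ± 19.9 CPM) and 51.4-fold (3.18 ± 0.482 to 163 ± 13.8 CPM). RSAD2 had a single count in the controls, so its ratio of 180 has a 95% counting interval from 31.9 to 7136. As its lower bound lies above the list's median, that median is 2.18 with either value. Of 7 tested IRF family members other than IRF4, 6 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00288, and adjusted p = 0.079 with an estimated correlation). IRF7, which drives interferon gene transcription, rose 4.01-fold (17.4 ± 7.10 to 70.0 ± 18.3 CPM), IRF1 1.91-fold and IRF9 1.80-fold, whereas IRF8, a B cell relative of IRF4, had a log2 fold change of 0.03 (SE 0.05, edgeR adjusted p = 0.607).

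Chemokine and immune surface genes had 14 members higher and 2 lower of 23 tested, and 15 and 2 adjusted over the list alone, with a median of 0.88 (camera adjusted p = 1.88e-06, and adjusted p = 0.0425 with an estimated correlation). The chemokines CCL3 and CCL4, whose copies in the genome can share reads, rose 38.4-fold to 18.9 ± 2.0 CPM and 23.3-fold to 31.8 ± 1.11 CPM. CD274, which encodes PD-L1, a ligand that restrains T cells, rose 3.67-fold, from 32.7 ± 2.06 to 120 ± 6.04 CPM. The T cell costimulator CD86 rose 2.25-fold. The NF-kB target list overlaps with these genes and moved in both directions, with 17 of 31 members higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.0119, and adjusted p = 0.439 with an estimated correlation). CD83, an activation marker, rose 2.39-fold, while TNFAIP2 fell 5.95-fold, from 122 ± 10.5 to 20.5 ± 1.36 CPM. In the JAK-STAT list 10 of 23 rose and 4 fell, and 11 and 4 adjusted over the list alone (camera adjusted p = 0.0312, and adjusted p = 0.121 with an estimated correlation). Camera did not call this list in series 2 alone (adjusted p = 0.105). Of its members STAT5A rose 12.7-fold to 16.9 ± 0.844 CPM, IL10 6.06-fold to 42.1 ± 4.77 CPM, IL2RB 3.12-fold and IL2RG 2.17-fold, while the kinase gene PIM1 fell 1.46-fold.

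Genes of antigen presentation rose by small amounts. Of 20 tested MHC class I genes 13 rose and 1 fell, and 14 and 1 adjusted over the list alone (median 0.35, camera adjusted p = 0.000175, and adjusted p = 0.079 with an estimated correlation). HLA-E rose 1.76-fold, the peptide transporter TAP2 1.59-fold, the class I transactivator NLRC5 1.55-fold and PSME2 1.46-fold. Of 15 class II genes 11 rose and 1 fell, and 12 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.000601, and adjusted p = 0.266 with an estimated correlation). HLA-DRB1 rose 1.57-fold and HLA-DQB1 2.37-fold, with the caution that HLA genes share reads and vary between people. CD74, the class II invariant chain, had a log2 fold change of 0.10 (SE 0.04, edgeR adjusted p = 0.0758), which was -0.02 after the GC trend was removed. It passed without control replicate 6 (0.13, adjusted p = 0.00385) or IRF4 shRNA replicate 6 (0.13, adjusted p = 0.0387), with a range over alternatives from 0.00197 to 0.668.

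Germinal centre genes were mostly higher, with 13 of 20 tested members up and 5 down, also adjusted over the list alone, and a median of 0.93 (camera adjusted p = 0.000161, and adjusted p = 0.079 with an estimated correlation). The adaptor STAP1 rose 23.7-fold, from 0.995 ± 0.265 to 23.6 ± 1.63 CPM, ITPKB 6.68-fold to 87.7 ± 13.9 CPM and KLHL6 2.93-fold to 83.8 ± 4.26 CPM. BCL6, the germinal centre repressor, rose 1.40-fold, from 37.4 ± 3.57 to 52.3 ± 2.87 CPM. Of 25 tested B cell identity genes 14 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.061, and fry upward, adjusted p = 5.38e-08). Among them the receptor genes CD22, CD72 and CD79A rose 2.04-, 1.92- and 1.71-fold, while POU2AF1, a coactivator of immunoglobulin transcription, fell 1.58-fold. Among receptor signalling genes, TLR7, a sensor of RNA, rose 2.17-fold, VAV1 1.99-fold and MYD88 1.60-fold (80.9 ± 3.59 to 130 ± 2.0 CPM).

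Plasma cell and secretory genes fell in 17 of 23 tested members and rose in 1, also adjusted over the list alone, with a median of -0.31 (camera adjusted p = 9.92e-06, and adjusted p = 0.0521 with an estimated correlation). XBP1, a transcription factor of secretory cells, fell 1.88-fold (77.9 ± 6.74 to 41.4 ± 5.09 CPM), its activating nuclease ERN1 3.97-fold (114 ± 5.31 to 28.8 ± 6.44 CPM) and the signal peptidase subunit SEC11C 2.01-fold. PRDM1, which encodes BLIMP1, had a log2 fold change of -0.19 (SE 0.06, edgeR adjusted p = 0.0146) whose adjusted p ran from 0.00201 to 0.235 over the alternatives. The fall of PRDM1 lay in series 1 (191 to 201 CPM, against 242 to 258 in controls). In series 2 its libraries overlapped (230 to 235 CPM, against 227 to 242 in controls). The member that rose was ZBP1 (4.06-fold), a nucleic acid sensor known to respond to interferon. Of 21 unfolded protein response genes 19 fell and 1 rose, also adjusted over the list alone (median -0.47, camera adjusted p = 2.69e-07, and adjusted p = 0.079 with an estimated correlation). SEL1L and EDEM1, of endoplasmic reticulum degradation, fell 2.36- and 2.05-fold, the chaperone HSP90B1 1.90-fold and PDIA6 1.69-fold. The list of ATF4 and amino acid response genes had 19 of 24 lower and 0 higher, and 20 and 0 adjusted over the list alone (median -0.40, camera adjusted p = 1.88e-06, and adjusted p = 0.079 with an estimated correlation). ALDH1L2, of mitochondrial folate metabolism, fell 4.31-fold (170 ± 11.6 to 39.5 ± 5.73 CPM), ATF5 2.54-fold (5119 ± 829 to 2014 ± 175 CPM), SHMT2 1.43-fold and WARS1 1.34-fold.

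Cytosolic ribosomal protein genes fell in 68 of 74 members, rose in 1, and fell in 69 and rose in 1 adjusted over the list alone (median -0.49, camera adjusted p = 1.68e-27, and adjusted p = 0.079 with an estimated correlation). RPL5 fell 1.84-fold (1668 ± 28.9 to 904 ± 18.7 CPM), RPL3 1.78-fold, RPLP0 1.75-fold and RPS6 1.64-fold. The elongation factor gene EEF1A1 and its processed pseudogene EEF1A1P5 fell by nearly the same log2 amount, 0.75 and 0.76, and RPL13AP5, a pseudogene copy of RPL13A, fell by 0.61. Reads of such genes and copies can be exchanged in counting, and the pseudogene share of counts was lower with IRF4 shRNA. Genes of MYC and ribosome biogenesis had 3 of 28 members higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.426, median -0.02), but 8 higher and 5 lower with library size alone (median 0.05), and 3 and 13 after the GC trend was removed. Fry called this list lower (adjusted p = 0.0388). MYC itself had a log2 fold change of -0.03 (SE 0.10, edgeR adjusted p = 0.833). It was 0.05 with library size alone and 0.14 without control replicates 5 and 6 (adjusted p = 0.0415, with a range over alternatives from 0.0415 to 0.945). Its sign also turned without control replicate 5 (0.02) or 6 (0.05) and without IRF4 shRNA replicate 5 or 6 (0.01 each).

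**Figure D2:**
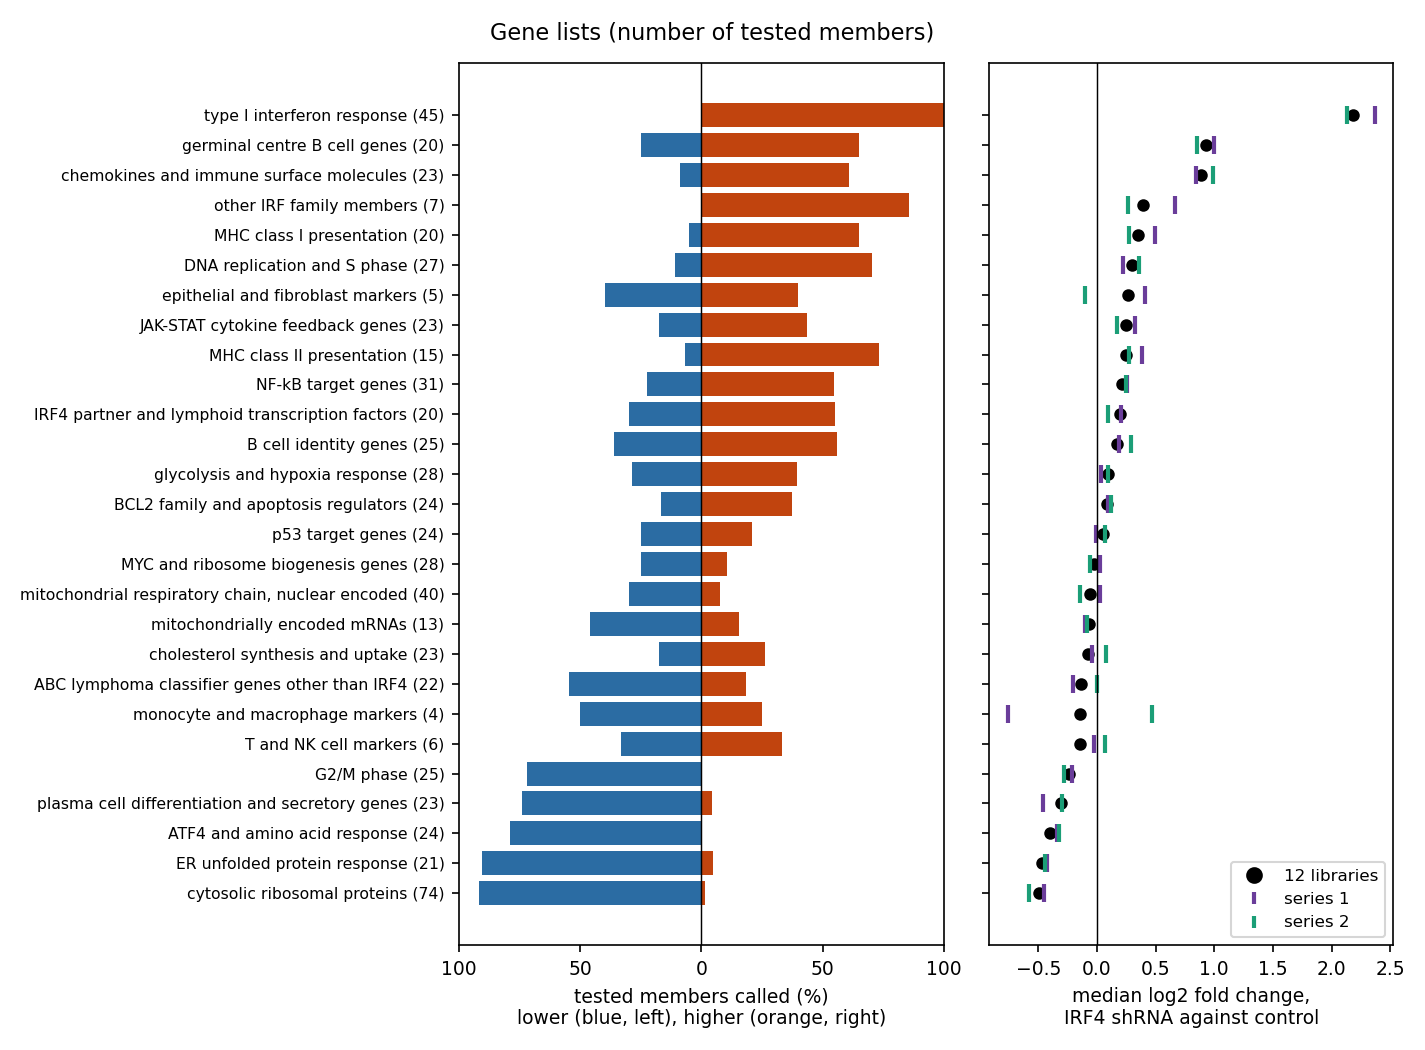
For each of 27 gene lists, with the number of tested members in brackets, the left panel gives the percentage of members called lower (blue) or higher (orange) with IRF4 shRNA and the right panel the median log2 fold change over 12 libraries (dot) and in library series 1 and 2 (ticks). The interferon list lies furthest to the right, at 2.18, and ribosomal proteins furthest to the left, at -0.49.

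Genes of DNA replication and of mitosis moved in opposite directions. Of 27 S phase genes 19 rose and 3 fell, also adjusted over the list alone (median 0.30, camera adjusted p = 4.95e-05, and adjusted p = 0.079 with an estimated correlation). TYMS, of thymidylate synthesis, rose 1.77-fold, FEN1 1.57-fold and MCM4 1.37-fold. Of 25 G2/M genes 18 fell and 0 rose, and 19 and 0 adjusted over the list alone (median -0.24, camera adjusted p = 0.000756, and adjusted p = 0.478 with an estimated correlation), but with library size alone 10 fell and 2 rose (median -0.16). CENPA fell from 12.6 ± 1.09 to 8.93 ± 0.579 CPM, CCNB1, the mitotic cyclin, fell 1.27-fold and AURKA 1.21-fold. Among 24 BCL2 family and apoptosis regulators 9 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.0869, and fry upward, adjusted p = 8.77e-08). The pro-apoptotic genes BIK and HRK rose 7.42-fold (1.62 ± 0.179 to 12 ± 2.35 CPM) and 1.99-fold (52.0 ± 2.28 to 103 ± 3.17 CPM), and the anti-apoptotic BCL2A1 rose 1.39-fold.

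The ABC lymphoma classifier genes other than IRF4 had 4 of 22 members higher and 12 lower, also adjusted over the list alone (median -0.14, camera adjusted p = 0.0795), but 7 higher and 8 lower with library size alone. Fry called this list lower (adjusted p = 0.00111), and camera did so in series 1 alone (adjusted p = 0.00348). Its median was -0.21 in series 1 and -0.003 in series 2. CREB3L2 fell 2.17-fold, from 280 ± 20 to 129 ± 19.9 CPM, RAB29 1.56-fold and CCND2, which encodes cyclin D2, 1.42-fold. Of 20 partner and lymphoid transcription factors 11 rose and 6 fell, and 12 and 6 adjusted over the list alone (camera adjusted p = 0.0634). Fry called them higher (adjusted p = 1.77e-05), and camera did so in series 1 alone (adjusted p = 0.0233) and without control replicates 5 and 6 (adjusted p = 0.0372). IKZF1 and IKZF3, which encode Ikaros and Aiolos, fell 1.22- and 1.19-fold and SPIB, an ETS partner of IRF4, 1.17-fold. The fall of IKZF3 lay mostly in series 1 (326 to 339 CPM, against 429 to 478 in controls). In series 2 the libraries overlapped (393 to 420 CPM, against 396 to 453 in controls). The calls of SPIB and IKZF3 were lost with counts summed per group and series (adjusted p = 0.0595 and 0.145, within ranges over alternatives of 5.95e-07 to 0.0595 and 0.000759 to 0.145). BATF, the AP-1 partner of IRF4, had a log2 fold change of 0.23 (SE 0.10, edgeR adjusted p = 0.0805). It was 0.38 without control replicates 5 and 6 (adjusted p = 0.0008, with a range over alternatives from 0.0008 to 0.249), and passed without replicate 5 (0.28, adjusted p = 0.0343) or replicate 6 (0.29, adjusted p = 0.0169) alone. BATF also passed with library size alone (0.30, adjusted p = 0.0202).

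Metabolic lists were not called by camera in the main comparison. Fry, which does not compare a list with other genes, called the respiratory chain (adjusted p = 0.00952) and mitochondrially encoded messenger RNAs (0.00714) lower and glycolysis (0.0417) higher. Camera called the respiratory chain lower after the GC trend was removed (adjusted p = 0.0342) and in series 2 alone (0.00784). Genes of cholesterol synthesis had 6 of 23 members higher and 4 lower, and 6 and 3 adjusted over the list alone, with a median of -0.08 although camera's direction was upward (adjusted p = 0.941). These counts were 7 and 1 with library size alone and 6 and 13 after the GC trend was removed. Glycolysis and hypoxia genes had 11 of 28 higher and 8 lower (camera adjusted p = 0.681), the nuclear encoded respiratory chain 3 of 40 higher and 12 lower (0.061), and p53 targets 5 of 24 higher and 6 lower (0.941), each with the same counts adjusted over the list alone. After the GC trend was removed 7 glycolysis genes were higher and 9 lower. Medians near 0 changed sign with the scaling, the respiratory chain from -0.06 to 0.02 with library size alone and p53 targets from 0.05 to -0.01 after the GC trend was removed. Of 13 mitochondrially encoded messenger RNAs 2 rose and 6 fell, also adjusted over the list alone (median -0.07, camera adjusted p = 0.174), but 4 rose and 3 fell with library size alone (median 0.01). MT-CO1 had a log2 fold change of 0.01 (SE 0.03, edgeR adjusted p = 0.765), of -0.02 without control replicates 5 and 6, and of -0.01 without control replicate 5 alone. It passed with library size alone (0.09, adjusted p = 0.0315, with a range over alternatives from 0.0315 to 0.996).

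Markers of other cell types moved in both directions. Of 6 tested T and NK cell markers 2 rose and 2 fell (median -0.15, mean 0.79, camera adjusted p = 0.876), of 4 monocyte and macrophage markers 1 rose and 2 fell (median -0.15, mean 0.22, 0.88), and of 5 epithelial and fibroblast markers 2 rose and 2 fell (median 0.27, mean 0.03, with camera downward, 0.628), each with the same counts adjusted over the list alone. Fry called T and NK markers higher (adjusted p = 0.000968) and epithelial and fibroblast markers lower (4.33e-07), but not monocyte markers (0.644). The cytotoxic genes GZMB and PRF1 went opposite ways, PRF1 from 3 counts in the controls to 370 with IRF4 shRNA, a ratio of 114 with a 95% counting interval from 38.8 to 557. CAV1 fell 4.94-fold, from 15.5 ± 1.62 to 3.14 ± 0.294 CPM, CDH1, which encodes E-cadherin, 2.49-fold, and ITGAM rose from 57 to 250 counts. Of the falls in CD4 and CD68 (log2 -0.39 and -0.44), both lost their call with counts summed per group and series (adjusted p = 0.162 and 0.0722, within ranges over alternatives of 0.00197 to 0.162 and 9.29e-05 to 0.0722). CD4 also lost it with a within-series correlation (adjusted p = 0.0728).

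**Figure D3:**
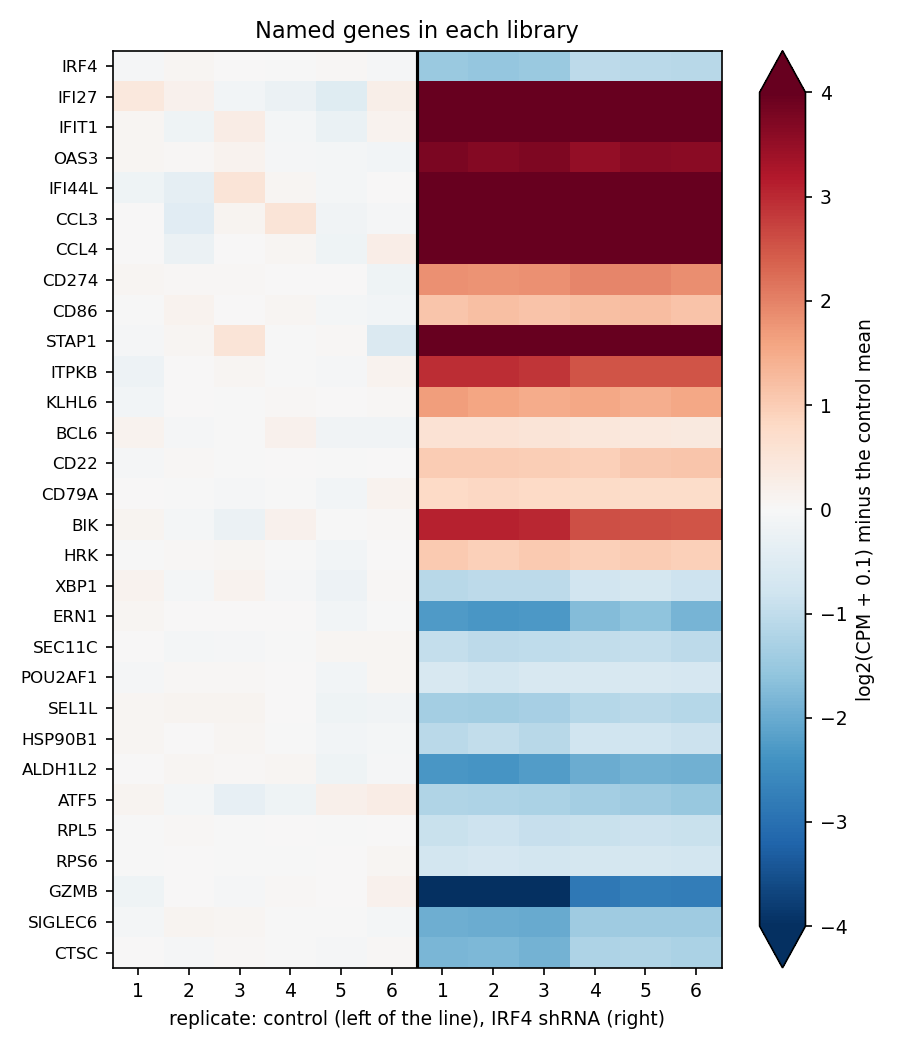
Each cell is log2(CPM + 0.1) of a gene in a library minus the mean of the 6 controls, from blue (lower) to red (higher), with colours saturated beyond 4. The IRF4 shRNA libraries share the direction of change in each gene shown, and GZMB, ERN1 and SIGLEC6 lie lower in replicates 1 to 3 (library series 1) than in replicates 4 to 6 (series 2).

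The next question was whether the contrast gave the same result in each library series, compared with the controls that carry its number. Only the library names match these controls to a series, and whether they belong with it is not given. In its deviation with GC, control replicate 4 of series 2 (rho -0.35) lay nearer to replicates 2 and 3 of series 1 (-0.47 and -0.50) than to replicates 5 and 6 (0.42 and 0.60). IFI27, IFIT1, OAS3, CCL3 and CCL4 rose in both series, and PTGDR, KCNA3, GZMB and CTSC fell in both. The rule that named IFI27, PTGDR, KCNA3 and GZMB required the same sign in both series. In series 1, 8362 of 16572 genes changed (4281 up, 4081 down), and in series 2, 6332 of 16614 (3354 up, 2978 down). Of 16290 genes tested in both, 2342 rose and 2027 fell in both, against 856 and 736 for independent lists, and 175 were called in opposite directions. Across genes, which are not independent replicates, effects of the series correlated with a Pearson r of 0.775 and a Spearman rho of 0.592. Of the 1379 genes with a 2-fold change over all libraries, 99.9% had the same sign in both series and 60.3% a larger effect in series 1. These genes were chosen by their effect over the same libraries, so the shared sign was nearly set by that choice.

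Several falls were deeper in series 1, where IRF4 was lower. GZMB had log2 fold changes of -4.48 in series 1 and -2.86 in series 2 (difference 1.60, edgeR interaction adjusted p = 1.98e-06), and MS4A6A of -3.50 and -1.80 (difference 1.69, adjusted p = 8.91e-05). CTSC, a lysosomal protease that activates granzymes, had -1.86 and -1.22, SIGLEC6, a sialic acid binding receptor, -2.03 and -1.38, and LHFPL2 -1.50 and -0.53. MAN1A1 (-0.72 and 0.19), RAB14 (-0.41 and 0.26), ADA2 (-0.18 and 0.86) and DENND3 (0.41 and -0.32) had effects of opposite sign, and DDX18 had -0.84 and -0.03. By the edgeR interaction test 2308 of 16437 genes differed, 834 with a higher and 1474 with a lower effect in series 2. Among the lists the interaction passed for 6 by camera and for 0 with an estimated correlation (smallest adjusted p = 0.297). Between the series, 3802 genes differed among the IRF4 shRNA libraries (DESeq2 3161). Among the controls edgeR called 0 genes, with 1940 at an unadjusted p under 0.05, and DESeq2 called 0. Controls varied more within a series (median SD of log2 CPM 0.139, against 0.0844 with IRF4 shRNA). A difference between their series was thus harder to detect, and 0 calls do not show that the controls agree. The interaction count was unstable, with 206 genes without control replicates 5 and 6. Leaving out control replicates 2, 3, 4, 5 and 6 singly gave 919, 828, 5357, 909 and 1187 genes, and leaving out IRF4 shRNA replicates 1 to 6 singly gave 861, 1190, 915, 1379, 785 and 736.

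**Figure D4:**
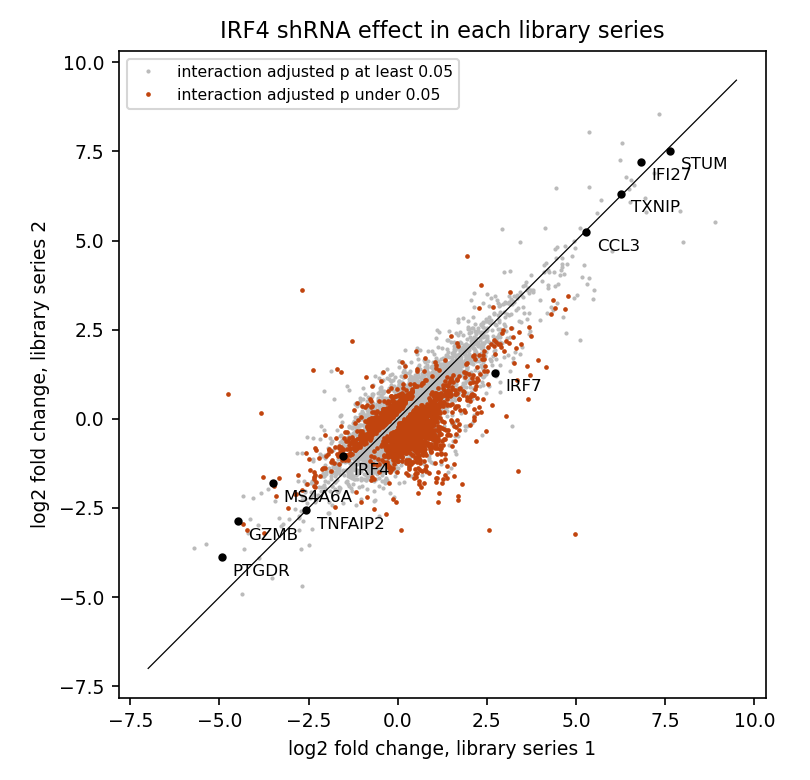
Log2 fold change of IRF4 shRNA against control in library series 1 (horizontal) and series 2 (vertical), with 1 point per gene and the line of equal effects; orange points have an interaction adjusted p under 0.05. Named genes far from the line include GZMB (-4.48, -2.86) and IRF7 (2.73, 1.30), while TXNIP (6.26, 6.32) and CCL3 (5.29, 5.24) lie on it. The place of IRF7 rests in part on control replicates 5 and 6 of series 2, where its level was above that of the other controls.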

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

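Of the tests in this part, the removal of control replicates 5 and 6, the removal of the GC trend and the comparison of marker levels in CPM were chosen after the result was seen. GZMB, IRF7 and IRF4 itself were among 36 named genes, of 123 tested, whose response to IRF4 shRNA differed between the library series by the edgeR interaction test. Up to 10 of the named genes were chosen for a small interaction p, so the share is not that of all genes, of which 2308 of 16437 differed. In the named genes that fell, the effect was mostly weaker in series 2, where IRF4 was lowered less. Given as series 2 minus series 1 on the log2 scale, the differences were 0.46 for IRF4, 1.60 for GZMB, 1.69 for MS4A6A, 1.02 for PTGDR, 1.09 for KCNA3, 0.51 for FRMPD1, 0.62 for CTSC, 0.64 for SIGLEC6, 0.95 for LHFPL2, 0.71 for CDH1, 0.76 for MRC1 and 0.69 for IL3RA. Among secretory and lymphoma genes they were 0.43 for XBP1, 0.64 for ERN1, 0.42 for SEL1L, 0.33 for EDEM1, 0.35 for HSP90B1, 0.47 for ALDH1L2, 0.35 for PRDM1, 0.37 for IKZF3, 0.55 for CREB3L2, 0.19 for RAB29 and 0.26 for CCND2. Genes with a lower value in series 2 were IRF7 (-1.45), BATF (-0.50), ITPKB (-0.49), VAV1 (-0.27), HLA-E (-0.23), BIK (-0.65), DENND3 (-0.75) and LILRA4 (-0.54). The value was higher in series 2 for CD83 (0.20), MAN1A1 (0.89), RAB14 (0.65), DDX18 (0.79) and ADA2 (1.03). The difference of IRF7 lay in both groups. Its level was 24.1 and 28.2 CPM in control replicates 5 and 6 of series 2, against at most 16.2 CPM in the other controls. With IRF4 shRNA it was 80.4 to 89.2 CPM in series 1 and 48.96 to 57.4 CPM in series 2. The -1.45 of IRF7 is thus not a difference of the IRF4 shRNA libraries alone. Over all genes called for the interaction, unlike the named ones, more had a lower value in series 2 (1474) than a higher one (834). Among differences of at least 2-fold these numbers were 438 and 54.

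Lists differed between the series too by camera, with interaction adjusted p of 9.92e-05 for ABC classifier genes, 0.000232 for ribosomal proteins, 0.0369 for the respiratory chain and 0.0485 each for plasma cell genes, germinal centre genes and monocyte markers. None of these 6 held with an estimated correlation (adjusted p from 0.297 to 0.764). By camera the value was higher in series 2 for ABC classifier genes, plasma cell genes and monocyte markers. It was lower in series 2 for ribosomal proteins, the respiratory chain and germinal centre genes. Ribosomal proteins thus fell more in series 2 (median -0.58, against -0.45 in series 1), where IRF4 was lowered less.

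The interaction count of 2308 genes exceeded all other drawn splits of the series labels (1 of 100 as large, highest other 1466). Only 100 of 200 distinct splits were drawn, and only 8 of the others kept the IRF4 shRNA libraries of a series together. Those 8 gave 76 to 1466 genes, while splits that mixed these libraries gave at most 1. Chance is thus not excluded for the interaction count. GC-dependent differences between libraries as the whole cause are argued against by the 1377 genes left after the GC trend was removed. The GC deviation of the IRF4 shRNA libraries followed the series, so a part of it in the interaction remains open. A response graded with the IRF4 level may contribute, since 68.9% of 1032 genes called for both tests had the smaller effect in series 2. This share covers only genes also called for the shRNA effect, and the other genes among the 2308 lie outside it. Rises of at least 2-fold were fewer in series 2 (899, against 1229 in series 1), but such falls were more numerous (600, against 521). Hairpin, culture and batch remain open beside a graded response, as the meaning of the series number is not given. Whether control replicates 5 and 6 set the difference cannot be told apart, since 206 genes passed without them, but 46 without control replicates 2 and 3 of series 1. The other pairs gave 1529 (replicates 1 and 2), 774 (1 and 3), 5348 (4 and 5) and 3930 (4 and 6), so among control pairs of series 2 only the removal of 5 and 6 lowered the count. Removal of control replicate 5 or 6 singly lowered it too (909 and 1187).

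The rise of interferon-induced genes such as IFI27, IFIT1 and OAS3 was weighed next. Tested T, NK and monocyte markers moved in both directions (median log2 fold change -0.148), which decides nothing about cells of another type. Of 21 such markers in the table the largest rise in mean level was 1.72 CPM (PRF1), against a median rise of 63.2 CPM in the interferon list, which argues against T, NK or monocytic cells as its source. LYZ, abundant in monocytes, had 4 counts in all controls and 44 with IRF4 shRNA. After the GC trend was removed the list's median was 2.10, which argues against GC differences as the whole cause. Delivery of an shRNA as such was shared with the controls, which carried a scramble shRNA and full IRF4. An effect particular to the IRF4 shRNA, such as its dose or other targets, cannot be told apart from loss of IRF4, because no library had an IRF4 shRNA with full IRF4 (interaction of the list with series, adjusted p = 0.236). Grading with the IRF4 level stayed undecided, since the list's median was lower in series 2 by a difference of -0.24 while the median of the members' own differences was 0.15.

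The number of changed genes, 7918, was far above the highest of the other drawn splits (278, with 1 of 100 as large). This argues against chance only if the libraries are independent samples, which the labels do not say. If the libraries of a group and series were repeats of 1 culture, 2 against 2 would leave too few splits to exclude chance. After the GC trend was removed 9166 genes passed, which argues against GC differences as the whole cause. With library size alone 1414 genes changed at least 2-fold, against 1379 with TMM. The mean TMM factors were close (0.975 in controls and 1.03 with IRF4 shRNA), so this exchange could hardly move the 2-fold count. Among all calls it moved rises from 3983 to 5257 and falls from 3935 to 2968, so the part of composition in small changes stays undecided. The count of 15 called lists was matched or passed in 7 of 100 splits (highest other 16), so chance cannot be excluded for the number of lists by this count. The other splits with as many lists kept 4 or 5 of the 6 IRF4 shRNA libraries on 1 side, and thus part of the real contrast, while the 39 splits with 3 on each side called at most 7. For series 1 (8362 genes, highest other split 0) and series 2 (6332 genes, highest other split 0), 1 of 10 splits was as large, and 10 splits are too few for a share under 0.05.

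Single libraries stood apart from the other 5 of their group in 11 of 256 groups tested, where chance flags about 1 in 20 groups (12.8 here). In controls these were HSPA1A at 15.5 CPM, KLHL6 at 26.7 CPM and BCL2A1 at 136 CPM in replicate 1, CENPA at 14.6 CPM in replicate 2, STAT5A at 0.915 CPM and MS4A6A at 34.1 CPM in replicate 3, TMEM229B at 0.0954 CPM in replicate 4 and CD274 at 28.7 CPM in replicate 6. In IRF4 shRNA replicate 5 they were IFI44 at 26.9 CPM, TXNIP at 172 CPM and WARS1 at 401 CPM.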

How the results depend on the processing

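The removal of control replicates 5 and 6 together, the GC correction and the replicate block for lists were chosen after the data were seen. The fall of IRF4 passed under each alternative run, and over 123 named genes 3147 of 3191 comparisons kept direction and side of the threshold, 15 lost the call, 14 gained it and 15 reversed. With counts summed per group and series, 4242 genes passed (2310 higher, 1932 lower), of which 3970 were shared with the 7918, with fewer samples by construction. Without a filter on low counts 2104 genes changed at least 2-fold, more genes being tested. The interaction gave 206 genes without control replicates 5 and 6 and 1377 with the GC correction. Camera called 2 lists with an estimated correlation and fry called 25, which tests another hypothesis. Reversed values, all of small size, were IRF8 -0.0066, DENND3 -0.0065 and CD74 -0.017 with the GC correction, MYC 0.047 and RAB14 0.024 with library size alone, and MYC 0.14 and MT-CO1 -0.021 without control replicates 5 and 6. With single libraries left out, the MYC log2 fold change ran from -0.070 to 0.050, the RAB14 log2 fold change from -0.091 to 0.021 and MT-CO1 from -0.0065 to 0.041. Over the same omissions the count of changed genes ran from 7544 to 8209 (higher 3842 to 4131, lower 3515 to 4078, at least 2-fold 1394 to 1471), series 1 from 7183 to 9194, series 2 from 4444 to 8611, the interaction from 736 to 5357 and IRF4 from -1.31 to -1.22. The replicate numbers did not pair the libraries, as 0 of 6 controls correlated best with their own number, and a block on title number gave 6942 genes, 6891 of them shared. Except where stated, the cause was not tested. Depth limited fold changes of genes with few control counts, such as TMEM229B.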

Other observations

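Both tests in this part were chosen after the result was seen. EGR2, EGR3 and FOS, immediate early genes that respond within minutes to receptor signals, were noticed among the rises, with log2 fold changes of 4.87, 4.72 and 3.19. A list of other immediate early and receptor activation genes was then written and tested without these. Of 17 tested members 13 rose and 0 fell, with a median of 1.77 (camera p = 3.00e-09, and 0.00636 with an estimated correlation). EGR1 rose from 2.43 ± 0.416 to 42.2 ± 4.66 CPM, CD69 from 2.41 ± 0.234 to 18.5 ± 0.314 CPM, DUSP4 from 1.66 ± 0.494 to 20.6 ± 0.706 CPM and NR4A1 from 6.75 ± 1.52 to 34.8 ± 3.98 CPM (SD, n = 6 each). The source of this rise was not tested.

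CLEC4C, GZMB and PTGDR, which fell, are also expressed in plasmacytoid dendritic cells, so a list of other genes of that cell type was tested. It did not fall as a group, with 5 of 14 tested members higher and 7 lower (median -0.09, camera p = 0.746, and 0.752 with an estimated correlation). IL3RA fell from 13.4 ± 0.850 to 3.43 ± 0.903 CPM, while LILRA4 rose from 4.57 ± 0.681 to 12.7 ± 1.79 CPM and PLAC8 from 11.4 ± 0.684 to 30.0 ± 2.5 CPM (SD, n = 6 each). Members that moved in both directions leave the idea undecided.

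IFNB1 and IFNG, which encode interferons, had few counts. IFNB1 had 4 counts in the 6 controls and 28 in the 6 IRF4 shRNA libraries, and IFNG had 0 and 10.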
